A study of Arabidopsis thaliana with 18 samples.

How the data were processed

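RNA sequencing of Arabidopsis thaliana seeds covered 6 groups, dry, imbibed and salt-imbibed seeds of Col-0 and floe1-1, with 3 libraries each. Per the labels, imbibed and salt seeds were sown on MS agar with 0 or 220 mM NaCl, kept dark and cold (4 °C) for 5 days and then lit for 4 hours at 22 °C, and libraries were sequenced as paired reads on an Illumina instrument. Groups and replicate numbers were taken from the sample titles. Labels do not say whether the libraries keep the strand or which seed lots were used.

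Per the submitters' processing notes, the authors used HISAT2 and DESeq2 with the TAIR10 build, whose versions, read counting and filters are not given in the sources used here. The files are 3 tables of the authors' own comparison of floe1-1 with Col-0, 1 per condition. Per the file headers, the authors deposited for each gene a mean normalized count, a signal that is never negative, averaged over the 6 libraries of a condition. The authors also deposited a log2 fold change and its standard error on the log2 scale. A Wald score for each gene, which equals the fold change divided by its standard error, is in the authors' deposited tables as well. The authors deposited a p-value and an adjusted p-value from DESeq2, and the adjusted values equal a Benjamini-Hochberg adjustment over the genes that have one, to within 1.5e-05. Genes with a low mean have no adjusted p: the smallest mean with one was 2.98 in dry, 5.86 in imbibed and 106 in salt seeds. No column of another sample is in the tables. All 279 organelle-encoded genes are listed at 0, so such reads were not counted or were removed before the tables were made.

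Because the tables hold the authors' statistics and no counts per library, the count tests planned before the data were examined could not be run. The planned fallback was used instead: the main calls are the authors' deposited adjusted p under 0.05. Comparisons of imbibed with dry and of salt with imbibed seeds within a genotype were not tested, since the tables were normalized separately. The difference of 2 fold changes was tested within this limit, as each fold change is formed inside 1 table: the difference was divided by the root of the summed squared standard errors, set against the normal distribution, 2-sided, and adjusted by Benjamini-Hochberg over genes with a mean of at least 10 in both tables. That form replaces the planned model of all libraries.

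Percent of Col-0, folds and 95% intervals were computed from the deposited log2 fold change and standard error. Group means were implied from the deposited mean and fold change with equal group sizes. Where the implied floe1-1 mean was under 3 normalized counts per library, only a lower bound of the fold is given, the Col-0 mean divided by 3. Bounds and intervals cover the error in the deposited values only, and the depth of each library is unknown here.

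A total of 19 gene lists with their identifiers were fixed before the data were examined. For each list with at least 5 genes at a mean of at least 10, the median log2 fold change was set against 10000 random lists of the same size, drawn within 20 classes of mean count, 2-sided, and adjusted by Benjamini-Hochberg over the lists of a condition. The smallest p that these draws can give is 2.0e-04. Random lists treat genes as independent, so the set test cameraPR of limma 3.58.1 in R 4.3.3 was added on the Wald scores with preset correlations of 0.01 and 0.05. An estimated correlation needs values per library and was not computed here. Counts adjusted over the list alone use the deposited p-values of its members with an adjusted p.

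Named genes followed a rule fixed before the data were examined. It names FLOE1, FLOE2 and FLOE3; the 10 largest folds in each direction among called genes with a mean of at least 20; up to 4 called members per list; the 5 smallest p in each direction for differences between conditions; and in salt ABI3, ABI5, DOG1, GA3OX1, GA3OX2, CYP707A2, EXPA2, NCED6 and RGL2. The rule also asked that libraries of both genotypes not overlap, which was not analysed here. AT4G28310, the other genes around FLOE1 and ILA, AT3G05610, and the list of genes in common between conditions were chosen after their values were seen.

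Gene symbols, positions, products, transcript lengths and GC content came from the RefSeq annotation of TAIR10.1, in which 32835 of the 33602 identifiers were found. The deposited tables carry no coordinates. Trends of the fold change with length or GC content were removed by a weighted cubic fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

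The steps were tested on simulated data made from the deposited standard errors, with 200 changed genes. Such data take those errors as right, so their shares of false calls do not test whether the deposited errors are too small. At a log2 change of 0.5, the adjusted calls recovered 37.5% of the changed genes in dry (17188 genes), 46.0% in imbibed (17643 genes) and 72.5% in salt seeds (11261 genes). The largest share of false calls at that change was 5.23%, in salt seeds. At a log2 change of 0.25 the calls recovered 2.0% in dry, 0.5% in imbibed and 13.0% in salt seeds. The genes tested reach down to a mean of 2.98 in dry and 5.86 in imbibed but only 106 in salt seeds. These shares therefore do not compare the conditions at equal counts. At a log2 change of 1, the difference between tables recovered 64.0% for imbibed minus dry (14600 genes), 71.0% for salt minus imbibed (15795 genes) and 64.5% for salt minus dry seeds (14733 genes), with up to 6.58% of false calls.

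Alternatives planned and run were no filter on low values, a mean of at least 50, and a log2 fold change of at least 1. Added after seeing the data were a floor of 10 for all tables, removal of length or GC trends, and the set test. Also added was scaling of the Wald scores and of the z of differences to a robust spread of 1 in 10 classes of mean count. That scaling first subtracted the median of each class, so it also recentred the values.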

Results

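The transcriptomes of Arabidopsis thaliana seeds were compared between the floe1-1 mutant and its wild type Col-0 in 3 states of hydration. FLOE1 encodes a prion-like protein of seeds that forms condensates when the seed takes up water. Seeds were dry, imbibed without added salt, or imbibed on 220 mM NaCl, and both imbibed sets had 5 days of stratification at 4 °C followed by 4 hours of light at 22 °C. Each of the 6 groups held 3 libraries, 18 in all. The files give, for each condition, the authors' own comparison of the 3 floe1-1 with the 3 Col-0 libraries, so values per library and the depth of each library are not analysed here. Each of the 3 tables lists 33602 genes, of which 22217 in dry, 22820 in imbibed and 23019 in salt seeds have a p-value. Among genes with a mean of at least 100 normalized counts, the median standard error of the log2 fold change was 0.12 in dry, 0.12 in imbibed and 0.11 in salt seeds. Nothing in the labels says whether replicates came from separate seed lots, so the p-values measure only the spread between these libraries.

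FLOE1 (AT4G28300) was the first gene examined, because it checks the genotype labels. It lies on chromosome 4 at 14014646 to 14017097 of the TAIR10.1 assembly, on the plus strand, with 2 annotated exons. The authors' deposited table of dry seeds put FLOE1 in floe1-1 at 3.66% of the Col-0 level (log2 fold change −4.77, standard error 0.11, adjusted p listed as 0). In imbibed seeds the authors' deposited table left 13.5% of the Col-0 level (log2 fold change −2.89, standard error 0.12, adjusted p = 2.7e-119). Salt seeds kept 10.7% in the authors' deposited table (log2 fold change −3.22, standard error 0.09, adjusted p = 5.1e-301). The loss was larger in dry seeds than in imbibed seeds by 1.88 on the log2 scale, with an adjusted p of 5.0e-26 for the difference between the authors' deposited tables. Its paralogs did not pass the threshold in any condition: the authors' deposited table of salt seeds gave a log2 fold change of −0.01 (standard error 0.10) for FLOE2 (AT5G14540) and −0.09 (standard error 0.12) for FLOE3 (AT3G01560). The largest change of either paralog in the authors' deposited table of dry seeds was the 0.03 of FLOE2 (standard error 0.10), and in imbibed seeds it was the 0.03 of FLOE3 (standard error 0.12).

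**Figure D1:**
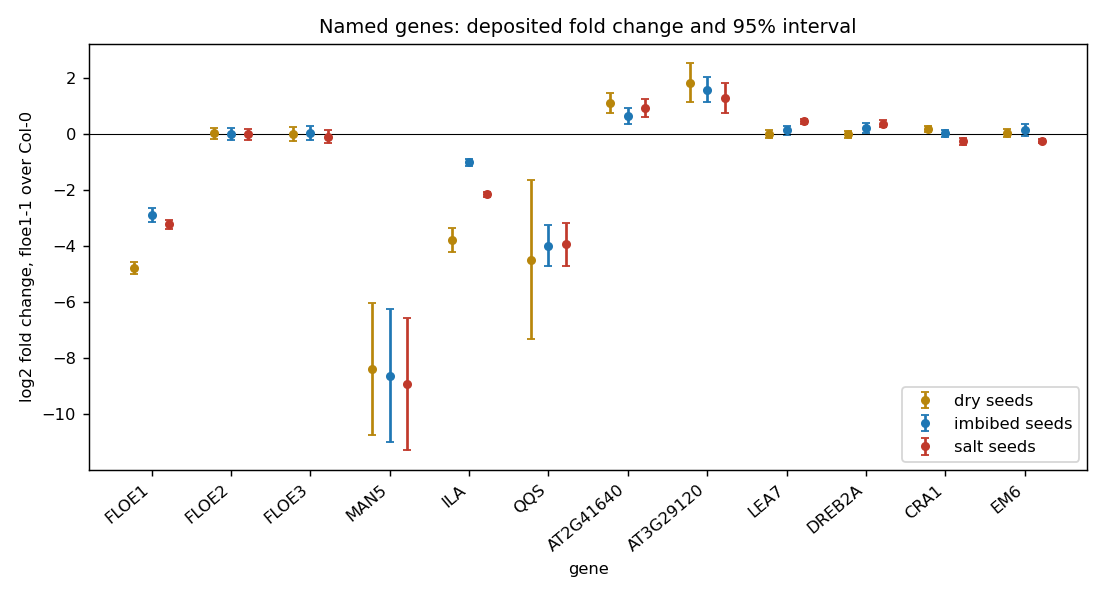
Log2 fold change of floe1-1 over Col-0 on the vertical axis for 12 named genes on the horizontal axis, as points with 95% intervals from the deposited standard errors, in dry, imbibed and salt seeds. FLOE1 lies at −4.77, −2.89 and −3.22, ILA at −3.78, −1.01 and −2.15, and both paralogs of FLOE1 lie near 0.

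In dry seeds, the question was whether the stored transcripts of the mutant differ from those of the wild type before any water is taken up. Few were called: 15 genes passed an adjusted p of 0.05 in the authors' deposited table, out of 17188 genes with an adjusted p. Of these 15, 5 were higher and 10 lower in floe1-1. Few calls do not mean few differences: of simulated genes changed by 0.25 on the log2 scale, 2.0% were called in dry seeds. Besides FLOE1, the authors' deposited table of dry seeds showed the largest loss for MAN5 (AT4G28320), which encodes an endo-beta-mannanase, an enzyme that breaks down cell wall mannans. Its Col-0 mean implied by the authors' deposited table was 127 normalized counts and its floe1-1 mean was below 3 per library, so that it was at least 42.2-fold lower, with an adjusted p of 1.6e-08. ILA (AT1G64790), which encodes the HEAT-repeat protein ILITYHIA, a relative of the translation regulator GCN1, fell to 7.28% of Col-0 in the authors' deposited table (log2 fold change −3.78, standard error 0.22, adjusted p = 3.8e-62).

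The other lower genes of dry seeds formed a small group. A set of 5 low-count genes, put together after their values were seen, held the arabinogalactan protein gene AGP23 (AT3G57690), AT3G01270, AT3G05610 and AT3G07820 of pectin-related enzyme families, and the uncharacterized AT3G28750. Their log2 fold changes in the authors' deposited table ran from −1.50 for AT3G01270 to −2.59 for AT3G05610, at mean normalized counts of 16 to 44.7. The peroxidase gene TPX2 (AT1G65970) fell by 0.47 on the log2 scale (standard error 0.09, adjusted p = 8.9e-04), and APO1 (AT1G64810), an organelle RNA-binding protein encoded near ILA, fell by 0.34 (standard error 0.08, adjusted p = 0.013) in the authors' deposited table. The 5 genes that rose in the authors' deposited table of dry seeds were KAN3 (AT4G17695, log2 fold change 2.09), the uncharacterized AT3G29120 (1.83), the glycosyltransferase AT2G41640 (1.11), the ethylene response factor gene ERF-1 (AT4G17500, 0.41) and the nitrile specifier gene NSP5 (AT5G48180, 0.35). Requiring a mean of at least 50 normalized counts left 7 calls, all of them among the 15.

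Among the fixed gene lists, dry seeds showed cytosolic ribosomal protein genes slightly higher in floe1-1. The median log2 fold change of 25 measured members was 0.10, with 24 above 0, against 10000 random lists matched on mean count (adjusted p = 0.0034). No member passed the threshold alone in the authors' deposited table, over all genes or adjusted over the list alone. The set test on the Wald statistics gave an adjusted p of 0.0072 at a correlation of 0.05. Photosynthesis and greening genes had a median of −0.27 (21 of 27 below 0, adjusted p = 0.0034) and the 5 measured defence and jasmonate genes a median of 0.31 (adjusted p = 0.0057), but neither held in the set test (adjusted p = 0.24 and 0.32 at a correlation of 0.01). Storage protein and oil body genes missed the threshold by their median of 0.07 (adjusted p = 0.061) and passed the set test (adjusted p = 0.0046 at a correlation of 0.01), and 4 of 13 were higher when adjusted over the list alone. Across 9888 genes with a mean of at least 100, the fold change in dry seeds fell with transcript length (Spearman rho −0.384 across genes, which are not independent replicates). With that trend removed, the ribosomal protein median was 0.07 (adjusted p = 0.0023) and the storage protein median 0.02 (adjusted p = 0.71).

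**Figure D2:**
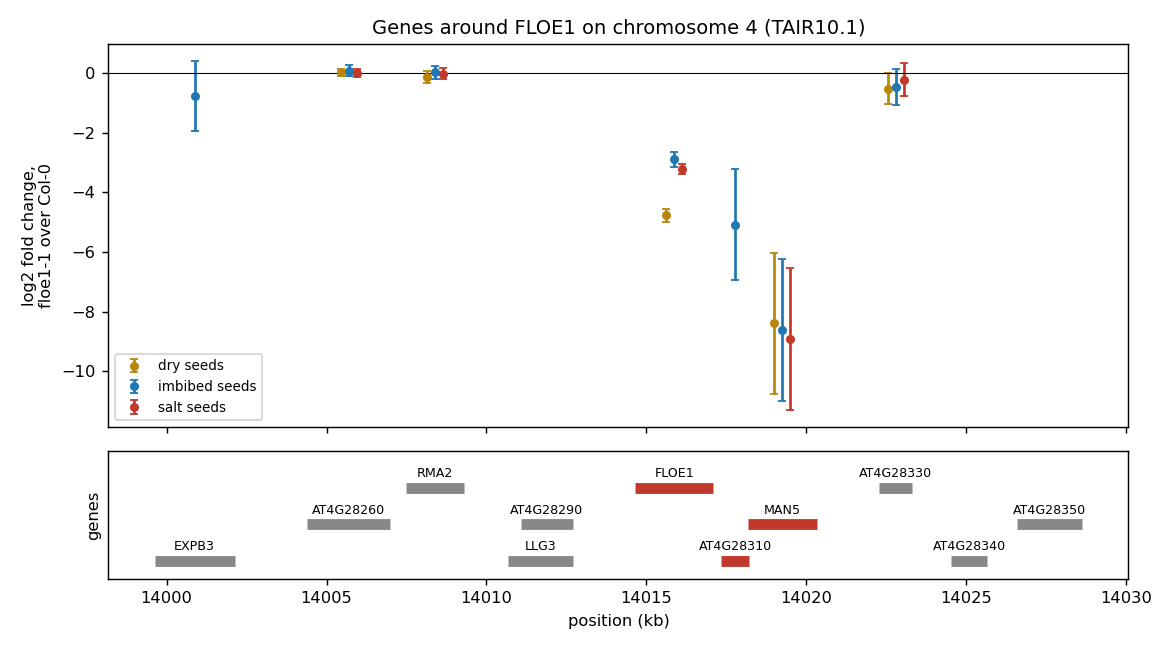
Genes of chromosome 4 around FLOE1 (TAIR10.1, position in kb), with the log2 fold change of floe1-1 over Col-0 and its 95% interval above, for each condition in which a gene had a mean of at least 10 normalized counts. FLOE1, AT4G28310 and MAN5 lie far below 0, and AT4G28260 and RMA2 lie near it. AT4G28330 lies at −0.53 in dry, −0.47 in imbibed and −0.22 in salt seeds (standard errors 0.27, 0.31 and 0.28). EXPB3, shown in imbibed seeds only, lies at −0.77 (standard error 0.59).

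In imbibed seeds the comparison asked how the mutant differs once water has entered and no salt is present. The authors' deposited table called 23 genes, 6 higher and 17 lower in floe1-1, out of 17643 genes with an adjusted p. FLOE1, ILA and MAN5 were again among the lower genes: the authors' deposited table put ILA at 49.6% of Col-0 (log2 fold change −1.01, standard error 0.07, adjusted p = 1.1e-43) and MAN5 at least 23.9-fold lower (adjusted p = 5.1e-09). AT4G28310, a gene annotated as a microtubule-associated protein between FLOE1 and MAN5 whose end overlaps that of MAN5, was at least 11-fold lower in the authors' deposited table (adjusted p = 1.3e-04). Without knowledge of the strand used in counting, reads from that overlap cannot be assigned to either gene.

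Several further genes had large losses in imbibed floe1-1 seeds. QQS (AT3G30720), an orphan gene that influences starch content and whose expression varies with DNA methylation among Arabidopsis lines, was at 6.31% of Col-0 in the authors' deposited table (log2 fold change −3.99, standard error 0.38, adjusted p = 2.6e-22). The adjacent genes AT4G09455 and MYB6 (AT4G09460) had log2 fold changes of −4.42 (standard error 0.34) and −2.71 (standard error 0.48) in the authors' deposited table. AT1G62460 was at least 22.5-fold lower in the authors' deposited table of imbibed seeds (adjusted p = 1.1e-07), and its near neighbour AT1G62480 had a log2 fold change of −2.16 (standard error 0.43). The expansin gene EXPA4 (AT2G39700), whose product loosens cell walls, fell by 0.83 on the log2 scale (standard error 0.15, adjusted p = 1.0e-04), and the tryptophan synthase gene TSA1 (AT3G54640) fell by 0.72 (standard error 0.12, adjusted p = 1.1e-06) in the authors' deposited table. Upward, the authors' deposited table called AT3G29120 (log2 fold change 1.58), AT5G33395 (1.31), AT1G67105 (0.89), AT1G20070 (0.78), AT2G41640 (0.65) and SIS (AT5G02020, 0.57), a gene of salt tolerance in seedlings. An absolute log2 fold change of at least 1 left 14 of the 23 calls.

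**Figure D3:**
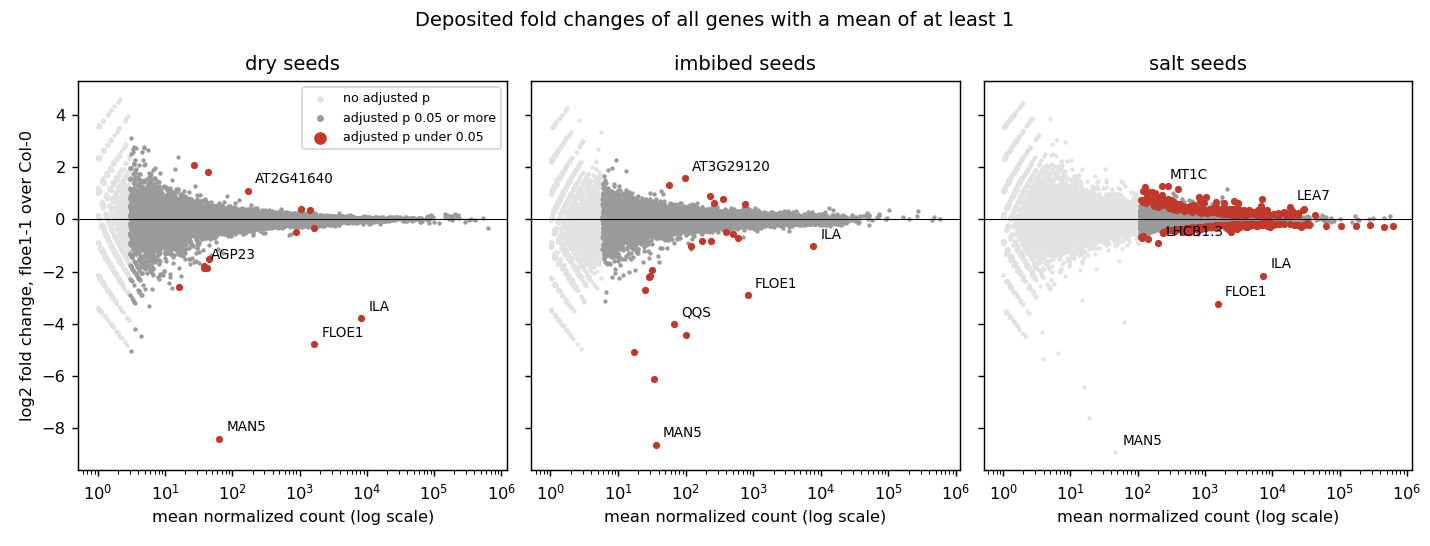
Log2 fold change of floe1-1 over Col-0 against the mean normalized count of each gene (log scale), in dry, imbibed and salt seeds, for genes with a mean of at least 1. Red points passed an adjusted p of 0.05 (15, 23 and 389 genes), dark grey points did not, and light grey points had no adjusted p.

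Of the gene lists in imbibed seeds, 8 of 18 tested passed the threshold. All 26 cytosolic ribosomal protein genes had a negative log2 fold change in floe1-1, with a median of −0.14 (adjusted p = 9.0e-04), although no member passed alone in the authors' deposited table. The cell wall loosening genes had a median of −0.17 (19 of 21 below 0, adjusted p = 9.0e-04), which stayed at −0.17 with MAN5 set to its bound, and 2 members passed alone, MAN5 and EXPA4. Photosynthesis and greening genes had a median of −0.23 (25 of 33 below 0, adjusted p = 9.0e-04) with no member called. Late embryogenesis abundant (LEA) genes, whose products protect dry cells, lay on the other side with a median of 0.14 (22 of 23 above 0, adjusted p = 9.0e-04), and heat shock genes had a median of 0.12 (14 of 17 above 0, adjusted p = 0.0072). These 5 lists also passed the set test at a correlation of 0.05, with the largest adjusted p of 0.0084 for the heat shock genes. Storage protein and oil body genes passed that set test too (adjusted p = 0.0087), but not by their median of 0.06 (adjusted p = 0.17). Gibberellin genes (median −0.10, adjusted p = 0.0082), auxin genes (−0.16, adjusted p = 0.0036) and salt transport and proline genes (0.13, adjusted p = 0.045) did not hold in the set test at a correlation of 0.01, where their adjusted p were 0.12, 0.12 and 0.074. Adjusted over the list alone, 1 LEA, 2 storage protein and 1 ethylene gene were higher, and 1 defence and jasmonate gene was lower.

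In salt, the comparison asked what the mutation changes when imbibition takes place on NaCl. The authors' deposited table called 389 genes, 250 higher and 139 lower in floe1-1, out of 11261 genes with an adjusted p. Most changes were small: the median size of the log2 fold change among them was 0.31, and 10 reached 1. After scaling the statistics to a robust spread of 1, an alternative chosen after seeing the data, 66 calls remained, 58 higher and 8 lower, all among the 389. Of the lower genes named for this comparison that have an adjusted p in salt, FLOE1, ILA, LHCB1.3 and AT2G40205 kept their call under that scaling and the others lost it. Of the higher ones, AT3G22910, AT4G36600, DREB2A, RD29A, RD29B, ZAT12, AHG1, PRODH1, SBT1.7, SDP1, ACX2, KAT2 and ACX1 lost it. ILA fell to 22.5% of Col-0 in the authors' deposited table (log2 fold change −2.15, standard error 0.05, adjusted p listed as 0). MAN5 had no adjusted p there because genes with a mean under 106 normalized counts were left out of the adjustment, and adjusting over all genes with a p gave 3.7e-10 for a level at least 30.8-fold below Col-0 in the authors' deposited table.

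Some genes of the response to water loss rose in salt-imbibed floe1-1 seeds. LEA7 (AT1G52690) rose to 1.38 times Col-0 in the authors' deposited table (log2 fold change 0.46, standard error 0.04, adjusted p = 4.6e-22). The list of ABA and osmotic stress response genes had a median of 0.26 (9 of 13 above 0, adjusted p = 0.0024), and 4 of its 9 members with an adjusted p passed alone, 5 when adjusted over the list alone. These 4 were ZAT12 (AT5G59820, log2 fold change 0.73), the transcription factor gene DREB2A (AT5G05410, 0.37), RD29A (AT5G52310, 0.30) and RD29B (AT5G52300, 0.26) in the authors' deposited table. LEA genes went both ways: 5 rose, with LEA7 and AT4G36600 (0.19) the largest, while EM6 (AT2G40170) fell by 0.25 (standard error 0.04, adjusted p = 9.3e-07) and M17 (AT2G41260) fell by 0.22 (standard error 0.06, adjusted p = 0.0082) in the authors' deposited table, and 16 members did not pass. Adjusted over the list alone, 6 LEA genes rose and 5 fell, and the list median was 0.03 (adjusted p = 0.22). Of the ABA signalling genes only the phosphatase gene AHG1 (AT5G51760) passed, with a log2 fold change of 0.18 in the authors' deposited table, and the list did not (median 0.07, adjusted p = 0.058). PRODH1 (AT3G30775), which degrades proline, rose by 0.29 (standard error 0.06, adjusted p = 1.6e-04) in the authors' deposited table, the only called member of salt transport and proline.

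Some genes that mobilise storage oil also rose in salt. Of the 19 storage lipid mobilisation genes with an adjusted p, 6 rose and 13 did not pass in the authors' deposited table, or 13 rose when adjusted over the list alone. The list median was 0.14 (18 of 21 above 0, adjusted p = 0.0018), and the set test gave an adjusted p of 3.6e-06 at a correlation of 0.05. The triacylglycerol lipase gene SDP1 (AT5G04040) led with a log2 fold change of 0.34 (standard error 0.09), followed by the beta-oxidation genes ACX2 (AT5G65110, 0.25), KAT2 (AT2G33150, 0.19) and ACX1 (AT4G16760, 0.19) in the authors' deposited table.

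Transcripts of storage proteins, photosynthesis and ribosomes were lower in salt-imbibed floe1-1 seeds. Of 13 storage protein and oil body genes, CRC (AT4G28520, log2 fold change −0.31), CRA1 (AT5G44120, −0.26) and SESA5 (AT5G54740, −0.23) fell in the authors' deposited table, 6 fell when adjusted over the list alone, and the list median was −0.11 (12 of 13 below 0, adjusted p = 0.022). Photosynthesis and greening had the lowest median of the lists, −0.36 (25 of 30 below 0, adjusted p = 0.0018). Its called members in the authors' deposited table were the light-harvesting gene LHCB1.3 (AT1G29930, −0.92, standard error 0.20), the Rubisco activase gene RCA (AT2G39730, −0.44, standard error 0.14) and RBCS1A (AT1G67090, −0.20, standard error 0.06), and 8 did not pass. Cytosolic ribosomal protein genes had a median of −0.09 (23 of 26 below 0, adjusted p = 0.013), with RPL4A (AT3G09630, −0.18) and RPS13A (AT4G00100, −0.18) called in the authors' deposited table. Heat shock genes as a list did not pass (median 0.00, adjusted p = 0.87), although HSP23.6 (AT4G25200, −0.40), HSP70T-2 (AT2G32120, −0.29) and HSP101 (AT1G74310, −0.23) fell in the authors' deposited table.

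A few hormone and dormancy genes were called in salt. The gibberellin synthesis gene KAO1 (AT1G05160, −0.38, standard error 0.11) and the DELLA gene RGL3 (AT5G17490, −0.35, standard error 0.11) fell in the authors' deposited table, 2 of 13 gibberellin genes with an adjusted p and also 2 when adjusted over the list alone, and PIF1 (AT2G20180), a phytochrome-interacting repressor of germination, fell by 0.21 (standard error 0.06, adjusted p = 0.024). The gibberellin list had a median of −0.09 (12 of 18 below 0, adjusted p = 0.054), which passed with the length trend removed (adjusted p = 0.038) and not in the set test (adjusted p = 0.13 at a correlation of 0.01). Dormancy and maturation regulators had a median of −0.11 (adjusted p = 0.029), which did not hold in the set test (adjusted p = 0.10 at a correlation of 0.01). The expansin gene EXPA10 (AT1G26770) rose by 0.52 (standard error 0.12, adjusted p = 0.0011) in the authors' deposited table, against a list median of −0.14 for cell wall loosening (adjusted p = 0.054). Of the regulators followed whatever their result, the authors' deposited table gave no call: ABI3 (AT3G24650) had a log2 fold change of −0.13 (standard error 0.04, adjusted p = 0.067), ABI5 (AT2G36270) 0.09, DOG1 (AT5G45830) 0.03, CYP707A2 (AT2G29090) 0.06, EXPA2 (AT5G05290) −0.14 and RGL2 (AT3G03450) −0.02. GA3OX1 (AT1G15550, −0.58, standard error 0.42), GA3OX2 (AT1G80340, 0.04, standard error 0.69) and NCED6 (AT3G24220, 0.21, standard error 0.29) lay under the count needed for an adjusted p in the authors' deposited table.

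The largest rises in salt among genes with a deposited adjusted p, and so with a mean of at least 106, were in genes outside the fixed lists. The authors' deposited table put at the top AT3G22910, a predicted calcium pump (2.46 times Col-0), the metallothionein gene MT1C (AT1G07610, log2 fold change 1.27, standard error 0.18), AT2G43120 (1.25, standard error 0.22) and ABCG31 (AT2G29940, 1.17, standard error 0.15), a transporter of the ABC family. They were followed in the authors' deposited table by CYP71B12 (AT5G25130, 1.11), SQE6 (AT5G24160, 1.05), AT1G26400 (1.03), the dehydrin gene ERD14 (AT1G76180, 1.01), AT2G41640 (0.94) and AT3G03240 (0.92). Within the same limit, the largest falls after FLOE1, ILA and LHCB1.3 were AT5G53740 (−0.74), SCPL20 (AT4G12910, −0.73), HPA1 (AT5G10330, −0.66), RLP42 (AT3G25020, −0.64), ACP2 (AT1G54580, −0.51), the ribosomal protein gene AT2G40205 (−0.50) and the basic helix-loop-helix gene AT1G68240 (−0.49) in the authors' deposited table.

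**Figure D4:**
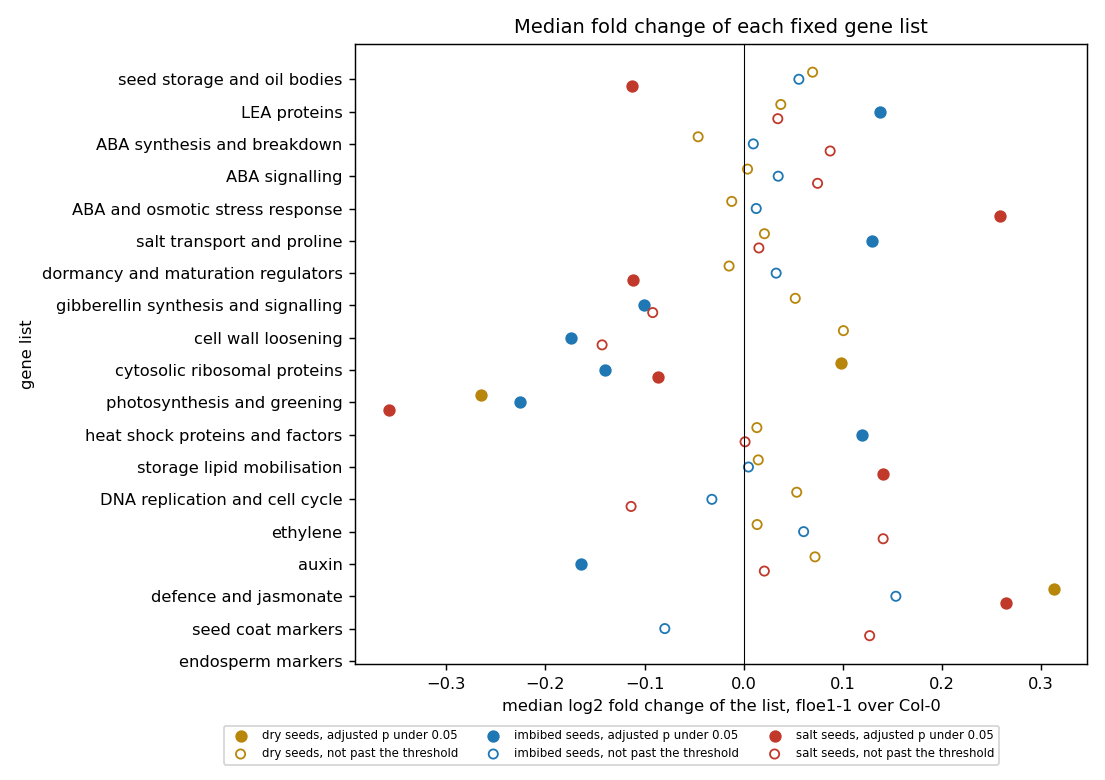
Median log2 fold change of floe1-1 over Col-0 (horizontal axis) for each of 19 fixed gene lists (vertical axis) in dry, imbibed and salt seeds. Filled points passed an adjusted p of 0.05 against 10000 matched random lists, which 3 lists did in dry, 8 in imbibed and 7 in salt seeds, and lists with fewer than 5 measured genes have no point.

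Of the remaining lists in salt, the 5 measured defence and jasmonate genes passed (median 0.27, adjusted p = 0.028) but not in the set test (adjusted p = 0.59 at a correlation of 0.01). Lists of ethylene (median 0.14, adjusted p = 0.081), DNA replication and cell cycle (−0.11, adjusted p = 0.11), ABA synthesis and breakdown (0.09, adjusted p = 0.33) and auxin genes (0.02, adjusted p = 0.87) did not pass.

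Seed tissue markers were also examined in each condition. The seed coat list could be tested in imbibed (median −0.08, adjusted p = 0.50) and salt seeds (median 0.13, adjusted p = 0.36) and passed in neither, but its member SBT1.7 (AT5G67360), a protease of seed coat mucilage, rose by 0.26 in salt (standard error 0.05, adjusted p = 8.2e-06) in the authors' deposited table. Endosperm markers had fewer than 5 measured genes in each table and were not tested. All 279 chloroplast-encoded and mitochondria-encoded genes are listed at 0 in the 3 tables, so their share gives no measure of RNA quality here.

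Whether the effect of floe1-1 depends on the state of the seed was tested as the difference of fold changes between tables. Between imbibed and dry seeds 3 of 14600 genes differed: ILA, whose log2 fold change was higher by 2.77 in imbibed seeds (adjusted p = 6.0e-29), FLOE1 and AT1G20070 (difference 0.68, adjusted p = 0.034), all from the authors' deposited tables. Between salt and imbibed seeds 11 of 15795 genes differed, 7 with a higher and 4 with a lower fold change in salt. The higher ones with the smallest p were the beta-glucosidase gene BGLU25 (AT3G03640, difference 0.59), the transporter gene UMAMIT20 (AT4G08290, 0.77), AT2G43120 (1.41), the aspartyl protease AT1G03220 (0.82) and the peroxidase AT5G39580 (1.74), and all 4 lower ones were ILA (−1.14), SESA5 (−0.48), JMJD5 (AT3G20810, −0.51) and AT5G55135 (−0.60), as differences of the authors' deposited tables. AATP1 (AT5G40010), named after its value was seen, had the largest difference, 2.85 (standard error 0.68, adjusted p = 0.038). Its log2 fold change was 1.43 in salt and −1.42 in imbibed seeds. With the z of the differences scaled to a robust spread of 1, an alternative chosen after seeing the data, 8 genes differed, 5 of them among the 11: ILA, UMAMIT20, AT2G43120, AT5G39580 and AATP1.

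Between salt and dry seeds 42 of 14733 genes differed, 40 of them with a higher fold change in salt. After FLOE1 and ILA, the largest statistics belonged to AT2G29340 (difference 0.68), CYP72A14 (AT3G14680, 0.93) and AT1G14940 (0.54), and ABCG31 (1.31), LEA7 (0.45) and DREB2A (0.38) were among the others in that direction in the authors' deposited tables. Both genes on the other side encode cruciferins, CRA1 (difference −0.43, adjusted p = 4.6e-04) and CRC (−0.49, adjusted p = 6.7e-04). Under the same scaling 19 genes differed, all with a higher fold change in salt and 18 of them among the 42, and LEA7, DREB2A, CRA1 and CRC lost their call (adjusted p = 0.099, 0.50, 0.10 and 0.11). For lists, in a test chosen after seeing the data, median differences were set against random lists, which treat genes as independent. Cytosolic ribosomal protein genes differed between imbibed and dry seeds (median difference −0.25, 0 of 25 above 0, adjusted p = 0.0034). Storage lipid mobilisation genes differed between salt and imbibed seeds (median difference 0.13, 19 of 21 above 0, adjusted p = 0.0018). Heat shock genes (−0.24), storage protein genes (−0.20) and LEA genes (−0.14) differed between salt and imbibed seeds in the other direction, each with an adjusted p of 0.0018, as did dormancy and photosynthesis genes (−0.14 for both, adjusted p = 0.0498). Between salt and dry seeds 6 lists differed: ABA and osmotic stress response (0.25) and storage lipid mobilisation genes (0.13) upward, and cell wall loosening (−0.36), photosynthesis (−0.22), storage protein (−0.20) and cytosolic ribosomal protein genes (−0.18) downward. No set test was run on these differences. The length trend, with a Spearman rho of −0.384 in dry and 0.102 in imbibed seeds, was not removed from any difference of genes or lists. It can enter the differences against dry seeds. With the trend removed within each table, the ribosomal protein median was 0.07 in dry and −0.13 in imbibed seeds.

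Some calls recurred between conditions. FLOE1, ILA and AT2G41640 were called in each of the authors' deposited tables. Of genes with an adjusted p in both tables, 2 higher and 3 lower genes were shared by dry and imbibed seeds. Independent lists would share 0.0019 and 0.0041. The higher ones were AT2G41640 and AT3G29120, and the lower ones ILA, FLOE1 and MAN5. FLOE1 carries the lesion and MAN5 lies near it, so their recurrence says nothing about other genes. All 4 higher genes of imbibed seeds that could be called in salt were called there (0.089 for independent lists): AT1G20070, AT1G67105, AT2G41640 and SIS. Of 4 lower genes of imbibed seeds that could be called in salt 2 were, FLOE1 and ILA, as were the same 2 of 4 lower genes of dry seeds, and 1 of 3 higher genes of dry seeds, AT2G41640 (0.066 for independent lists). No library enters more than 1 table. Across genes with a mean of at least 100 in both tables, without FLOE1 and ILA, fold changes were weakly correlated between conditions. Pearson r was −0.068 for imbibed and dry (9424 genes), 0.072 for salt and imbibed (11206 genes) and 0.077 for salt and dry seeds (9534 genes). Among genes with such a mean, the robust spread of the Wald score was 0.896 in dry, 0.910 in imbibed and 1.18 in salt seeds. Error alone gives a spread of 1, so a weak correlation cannot tell different effects from effects lost in error. Over all calls, the 250 genes that rose in salt had a positive fold change in 69.6% of cases in imbibed and 57.6% in dry seeds, and the 139 that fell had a negative one in 51.8% and 43.9%, in the authors' deposited tables.

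Levels between conditions were set side by side without a test, because the 3 tables were normalized separately and each mean pools both genotypes. LEA transcripts took 11.5% of the summed means in dry, 3.13% in imbibed and 6.85% in salt seeds. The share of heat shock genes was 6.74 times as high in dry as in imbibed seeds, and 1.45 times as high in salt as in imbibed seeds. Cytosolic ribosomal protein genes went from 0.155% in dry to 1.29% in imbibed and 0.721% in salt seeds, with all 26 members higher in imbibed than in dry seeds. Cell wall loosening genes took 0.352% in imbibed but 0.0149% in salt and 0.0016% in dry seeds, and the expansin gene EXPA2 had mean normalized counts of 1.36 in dry, 11921 in imbibed and 129 in salt seeds. GA3OX1, which makes active gibberellin, was listed at 0 in dry seeds and had a mean of 1225 in imbibed and 32.0 in salt seeds in the authors' deposited tables. Salt seeds did not lie between both other states for each list: storage protein and oil body genes took 9.38% in dry, 8.05% in imbibed and 10.5% in salt seeds.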

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

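The tests of the pattern at FLOE1 and ILA, the common floor and the scaling of statistics were chosen only after the results were seen. Removal of length and GC trends was added after seeing the data, but what it should show was written before its own values were computed. The stage and pollen tests were also written before their own values were computed, the pollen list after the 5 called genes were seen. The results listed first met the test of a difference between conditions, as the difference of the log2 fold change of floe1-1 over Col-0 between the authors' deposited tables.

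Between imbibed and dry seeds 3 genes differed: ILA by 2.77, FLOE1 by 1.88 and AT1G20070 by 0.68. Between salt and imbibed seeds 11 genes differed, among them AATP1 by 2.85, AT5G39580 by 1.74, AT2G43120 by 1.41, AT1G03220 by 0.82, UMAMIT20 by 0.77, BGLU25 by 0.59 and SBT1.7 by 0.38 upward, and ILA by −1.14, AT5G55135 by −0.60, JMJD5 by −0.51 and SESA5 by −0.48 downward. Between salt and dry seeds 42 genes differed. Upward these included ILA by 1.63, FLOE1 by 1.55, ABCG31 by 1.31, CYP71B12 by 1.21, AT3G03240 by 1.00, CYP72A14 by 0.93, AT1G26400 by 0.91 and AT1G03220 by 0.87. Smaller upward differences were AT2G29340 by 0.68, BGLU25 by 0.64, TPX2 by 0.61, UMAMIT20 by 0.59, AT1G14940 by 0.54, LEA7 by 0.45, DREB2A by 0.38 and SBT1.7 by 0.36. The downward ones were CRC by −0.49 and CRA1 by −0.43.

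FLOE1 and ILA were lower in floe1-1 in each condition, as was MAN5 downstream of FLOE1, and AT4G28310 between FLOE1 and MAN5 was lower in imbibed seeds. Within 5 genes of FLOE1, 2 other genes had a log2 fold change under −1 at a p under 0.001, which 0.0227% of windows around other expressed genes matched; this is consistent with a lesion at FLOE1 that also reaches both neighbours, found and tested on the same data. ILA lies on chromosome 1, which argues against linkage to FLOE1. A lesion at ILA that reaches its neighbours stays open. Within 5 genes of ILA, 0 others met the criterion, but the adjacent genes had means of at most 1.19 and could not meet it. APO1 had −0.34 in dry (adjusted p = 0.013), −0.22 in imbibed and −0.17 in salt seeds in the authors' deposited tables. AT1G64820, next to APO1, had −0.61 in dry (standard error 0.17), 0.96 in imbibed (standard error 0.68) and −0.43 in salt seeds (standard error 0.29). In the same order, DSS1(I) had −0.002, 0.03 and −0.08, AT1G64840 had 0.02, −0.10 and −0.01, and TUA1 had −0.44, 0.04 and 0.01. The share of ILA left was not the same everywhere, 7.28% in dry, 49.6% in imbibed and 22.5% in salt seeds of the authors' deposited tables, with a largest z of 13.7 in size between salt and imbibed seeds (FLOE1 −2.19 there); a single lesion at ILA with a varying effect stays open, since FLOE1, which carries a lesion, also varied (z of 11.4 between imbibed and dry seeds). A second change in the floe1-1 line that lowers ILA alone, and an effect of FLOE1 on ILA, were not tested, and the design with 1 mutant line cannot separate them.

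The 389 calls in salt against 15 in dry and 23 in imbibed seeds are the second pattern. Removing the length trend left 372, removing the GC trend 376 and a common floor of 10 left 383, so none of these accounts for the gap, the highest other count being 23, 22 and 23. Scaling each table's statistics to a robust spread of 1 left 66 in salt against 34 in dry and 29 in imbibed seeds. Understated errors in salt may therefore account for most of the count, though not for the whole gap. With 200 changed genes in simulated salt data, scaling recovered 70.0% at a log2 change of 0.5, against 72.5% unscaled. Those data take the deposited errors as right, so their spread is near 1 by construction and scaling alters little. They cannot tell understated errors from real effects lost by scaling. Whether scaling removes small real effects when many more genes change was not tested, so such a loss stays possible. A shift of floe1-1 along the path of imbibition in salt stays open: the salt fold change had a Spearman rho of −0.136 across 9357 genes with the change from dry to imbibed level, against −0.361 in imbibed and −0.051 in dry seeds. Other splits of the 6 libraries of a table could not be counted without values per library, so chance in the grouping was not examined.

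A set of 5 low-count genes among the 10 that fell in dry seeds, linked to pollen by background knowledge rather than by a table, is the third pattern. In a list of 26 further pollen genes written before their values were seen, 17 had a mean of at least 5 in dry seeds, 16 of them below 0, with a median of −1.14 (quartiles −1.64 and −0.31). The list was not uniform: AGP24 (0.14), PPME1 (−0.02), AGP6 (−0.11), AGP11 (−0.25), AHA8 (−0.31), ANX1 (−0.32) and TUA1 (−0.44) lay nearer to 0, and whether seed tissue adds to their counts was not tested. By the same rule the median was 0.03 in imbibed (4 of 9 below 0) and 0.12 in salt seeds (2 of 8 below 0). These medians rest on other subsets of the list. VGD1, VGDH1, VGDH2, AT5G07430, SKS11, PGA4 and AT3G07850, at −1.14 to −3.32 in dry seeds, did not reach a mean of 5 there. Whether the fall is confined to dry seeds therefore cannot be told. Less pollen or floral debris in the dry floe1-1 samples is a candidate explanation, and a difference of genotype in dry seeds was not separated from it.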

How the results depend on the processing

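The floor of 10, the scaling, the trend removals, the set tests and the mean of at least 50 for differences between conditions were chosen after seeing the data; the other settings were planned. Counts of changed genes within a condition moved by more than 1.5 times in 5 cases. A mean of at least 50 left 7 calls in dry seeds, where 5 of the lower genes, with a mean of 16 to 44.7, lie below that limit. An absolute log2 fold change of at least 1 left 14 in imbibed and 10 in salt seeds, by construction, as small changes are removed. Scaling the statistics gave 34 in dry and 66 in salt seeds, where the robust spread of the statistic was 0.896 in dry and 1.18 in salt seeds among genes with a mean of at least 100, and 1.01 and 1.63 among genes with a mean of at least 1000; the cause of that spread was not tested. All other settings run kept these counts within 1.5 times: 11 to 15 in dry, 16 to 29 in imbibed and at least 335 in salt seeds. Counts of genes that differ between conditions, run without a filter, with a mean of at least 50 and with the z scaled, were 3 to 4 for imbibed and dry and 8 to 11 for salt and imbibed seeds. For salt and dry seeds they were 36 without a filter, 49 with a mean of at least 50 and 19 with the z scaled, and the cause of the last was not tested. Called lists went from 3 to 2 in dry, from 8 to 6 in imbibed and from 7 to 5 in salt seeds in the set test, and were 3, 7 and 8 with the length trend removed. No named gene or list that was called changed direction in any setting, while FLOE2 and some lists that were not called, among them cell wall loosening in dry seeds (median 0.10, lower in the set test), changed sign with a trend removed or in the set test; the setting that lost the largest number of single calls was the scaling, with 35, among them in salt most of the lower genes named in the report (CRC, CRA1, SESA5, EM6, M17, RCA, RBCS1A, RPL4A, RPS13A, HSP101, KAO1, RGL3 and PIF1, for example). No paired analysis was possible because the tables hold no values per library, and for the same reason the replicate block, leaving out each replicate, other count tests and normalizations, pseudocounts, a fit of all 18 libraries and an estimated correlation between genes were not run. Low counts limit the salt table most, in which genes with a mean under 106 have no adjusted p. Without that filter 335 genes were called there, 311 of them among the 389, and 24 were gained, among them MAN5, QQS, AT1G62460, AT4G09455, MYB6, AT3G29120 and AT5G33395.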

Other observations

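Grouping genes by the opening words of their annotated product, a test chosen after the results were seen, gave 4 families past an adjusted p of 0.05 over the 406 families tested per direction in salt seeds. Ribosomal proteins held 25 of the 139 genes that fell (2.99 by chance among 242 tested, adjusted p = 6.7e-14). Among genes that rose, polyketide cyclase/dehydrase and lipid transport proteins held 7 of 13 tested (adjusted p = 1.5e-06), with AT1G14930, AT1G14940, AT1G14950 and AT1G14960 bearing consecutive locus numbers. Cytochrome P450 genes held 11 of 52 (adjusted p = 2.8e-06), among them CYP72A13, CYP72A14 and CYP72A15, and LEA-related proteins held 7 of 29 (adjusted p = 3.4e-04). Neighbouring copies of similar sequence can share reads, so these family counts are not counts of independent genes. They rest on the 389 unscaled calls. The background was all 11261 genes with an adjusted p, not matched on mean count. The robust spread of the Wald score in salt seeds was 1.18 at a mean of at least 100 and 1.63 at 1000 or more. Families of abundant transcripts can therefore exceed the chance counts given here for that reason alone. Scaling left 58 higher and 8 lower calls in salt seeds, and the families were not tested again on those. No family passed in dry or imbibed seeds.

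Genes that rise on imbibition tended to be lower in imbibed floe1-1 seeds. The fold change of imbibed seeds had a Spearman rho of −0.361 across 9357 genes with the log2 ratio of imbibed to dry level, and some lists went the same way: ribosomal protein, cell wall and photosynthesis genes, all higher in imbibed than in dry seeds by their median level, had negative medians in floe1-1, and LEA and heat shock genes, lower in imbibed seeds, had positive ones. Salt transport and proline genes, higher in imbibed seeds by their median level, had a positive median (0.13), as did defence and jasmonate genes (0.15), and storage lipid mobilisation genes had 0.00, so the relation does not hold for each list. Genes are not independent and no value per library is analysed here, so no p is attached to this relation, and a single library could carry it, as the length relation of dry seeds (rho −0.384) and the stage relation of salt seeds (rho −0.136) could be carried.

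Several genes with large losses in imbibed floe1-1 seeds had them in salt seeds too. QQS was at 6.31% of Col-0 in imbibed and 6.56% in salt seeds of the authors' deposited tables. AT4G09455 and MYB6, side by side on chromosome 4 at 5987419 to 5991819 and 5992908 to 5994258 of TAIR10.1, had log2 fold changes of −4.42 and −2.71 in imbibed seeds, and were at least 10.6-fold and 4.24-fold lower in salt seeds, in the authors' deposited tables. These bounds do not show a deeper loss in salt. AT1G62460, on chromosome 1 at 23118657 to 23123058, was at least 22.5-fold lower in imbibed and 12.4-fold lower in salt seeds of the authors' deposited tables. Its near neighbour AT1G62480 had −2.16 in imbibed but 0.46 in salt seeds (standard error 1.43), at a mean of 2.31 that is too low to tell. In the other direction AT3G29120 had 1.83 in dry and 1.58 in imbibed seeds, and AT2G41640 had 1.11 in dry, 0.65 in imbibed and 0.94 in salt seeds, in the authors' deposited tables. No cause of these differences between the lines was tested.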
